A study of Homo sapiens with 4 samples.

How the data were processed

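RNA of 4 samples of HEK-293 cells was measured on 3' expression arrays with 54675 probe sets. Per the labels' protocols, cells were transfected with 10 µg of plasmid and 50 µl of a lipid reagent, the medium was renewed after 16 h, cells were harvested at 72 h, and biotin-labelled cRNA was made from 6 µg of total RNA. The groups, taken from the titles, were empty vector (2 arrays) and Rec (2 arrays). The deposited values are log2 expression values, 1 per probe set and array. The submitters' processing notes name RMA and limma 3.16.6 without saying what each was used for. RMA corrects background, equalises distributions between arrays and summarises probes on the log2 scale. Whether a background correction by GC content was used is not given in the sources used here. In the deposited log2 values 18332 probe sets (33.5%) sat at the floor of 2.19 on all 4 arrays, so differences between dim transcripts are compressed and values at the floor have no order.

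Everything from the deposited log2 values onward was computed in R 4.3.3 with limma 3.58.1. The 62 control probe sets were left out of the tests, which left 54613. Gene names came from a reference table of the platform's probe sets, checked for newer symbols by gene identifier: 41091 probe sets had 1 gene, 1801 had several and 11721 had none, and 0 symbols were changed. No genome build is named for the arrays, so no coordinates are given. A gene was represented by its probe set with the highest mean over the 4 arrays among those annotated to 1 gene, which gave 19775 genes. Genes measured only by probe sets annotated to several genes are therefore missing from the lists. Probe sets are called brighter where their mean was at or above the median of all, 2.47, which is only a little above the floor.

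The comparison was a limma fit of group (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. A rule of size without a test took probe sets at least 2-fold apart with both Rec arrays on 1 side of both empty-vector arrays. Gene lists, 30 in number and with at least 5 measured genes, were tested with camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over the lists), which compares a list with all other genes, and beside it with camera with an estimated correlation and with fry. The lists were Rec binding partners, MYC targets, androgen response, interferon response, NF-kB and cytokine targets, p53 targets, DNA replication, mitosis, replication-dependent histones, apoptosis, unfolded protein response, heat shock response, oxidative stress and metallothioneins, immediate early genes, ribosomal proteins, translation factors, mRNA export and nuclear pore, splicing factors, pluripotency and germ cell, cancer testis antigens, retroelement silencing, matrix and adhesion, epithelial-mesenchymal transition and TGF-beta, WNT pathway, cholesterol synthesis, hypoxia and glycolysis, oxidative phosphorylation, neuronal genes, kidney and epithelial genes, and genes of other tissues. The tests, lists, alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to have been made afterwards.

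Genes were named by a fixed rule: those past the threshold with no overlap, and, since fewer than 10 passed in a direction, the genes with the smallest unadjusted p and no overlap up to 10 per direction; of each list, up to 3 members with the smallest unadjusted p where none passed; the Rec partners, MYC and IFITM1; and genes whose symbol begins with ERV or HERV. A binding partner that the rule names is not reported here.

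The fit and the list tests were tested on simulated arrays with the real means and residual spread, in 3 draws with changes planted in well expressed probe sets. Over all 54613 probe sets the fit recovered 2% of 300 changes of 1 log2 unit and 6.33% of 300 changes of 2 log2 units. Over the 27307 brighter ones it recovered 6.67% and 21.3%. A list shifted by 0.3 was called in 3 of 3 draws and 0 other lists were called, with genes drawn independently of each other, which real genes are not.

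The alternatives were a filter on dim probe sets, quantile normalization again, centring each array on its median, eBayes with trend and robust fitting, the sample number as a block, leaving out each array in turn, the mean of all probe sets of a gene, the other list tests, and a minimum of 1.5-fold. A filter against the floor, and leaving out each array among brighter probe sets, were added after the data were seen. With 1 array left out, the lone array of a group is assumed to vary like the other group.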

Results

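Transcript levels were measured in HEK-293, a line of human embryonic kidney cells that takes up plasmid DNA readily, 72 h after transfection with a pCDNA3 plasmid encoding Rec or with the same vector without an insert. Rec is a small protein of the endogenous retrovirus group HERV-K(HML-2) that carries unspliced viral RNA out of the nucleus. Each group held 2 arrays, and the comparison asked which host transcripts differed between cells that received the Rec plasmid and cells that received the empty vector. Nothing in the labels says that the arrays of a group came from separate cultures, so p-values measured the spread between these samples only. Gene values below are means over n = 2 arrays ± SD on the log2 scale, with empty vector first and Rec second. The number of arrays limited the precision of every value.

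The arrays had similar distributions, with medians between 2.45 and 2.48 and upper quartiles between 7.78 and 7.88. Between 34.4% and 35.5% of the values of an array lay at a shared floor of 2.19. Rec array 1 stood apart from the rest: 709 of the 27307 brighter probe sets lay over 1 log2 unit from the median of the 4 arrays there, against 45 on Rec array 2 and 19 and 29 on the empty-vector arrays. Spiked-in bacterial and phage control transcripts, which do not come from the cells, were higher by a median of 1.36 log2 units on Rec array 1 than in the empty-vector mean, and by 0.15 on Rec array 2. The level of the Rec transcript was not analysed here.

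**Figure D1:**
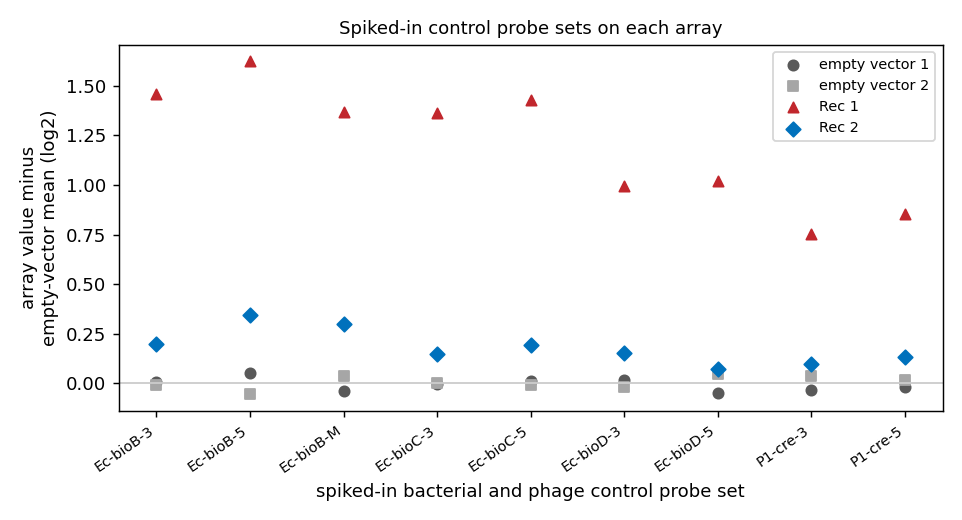
Value of each of 9 spiked-in control probe sets on each of the 4 arrays minus the mean of the empty-vector arrays (log2). Rec array 1 lies between 0.75 and 1.62 and Rec array 2 between 0.073 and 0.35.

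DNAI4, an intermediate chain of axonemal dynein, had the largest difference among the 23 genes whose brightest probe set was at least 2-fold higher with Rec with no overlap between the groups. Its brightest probe set measured 4.91 ± 0.11 and 7.70 ± 0.032, a difference of 2.79 with a standard error of 0.075, and limma gave an adjusted p of 1. A dimmer probe set of DNAI4 differed by 1.55, and the other 3 lay near the floor on all 4 arrays. MAP2K5, the kinase upstream of ERK5, measured 7.63 ± 0.33 and 9.49 ± 0.44, but 3 other expressed probe sets of MAP2K5 differed by −0.073, −0.17 and −0.38. MAP2K5 was chosen after its values were seen.

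No gene passed the test. Limma with Benjamini-Hochberg adjustment over 54613 probe sets called 0 probe sets higher and 0 lower with Rec, and 0 genes in either direction. At an unadjusted p under 0.05 it listed 1417 probe sets, fewer than the 2730.65 expected by chance. With a variance trend and robust fitting limma called 0 and listed 1262, against the same 2730.65. Probe sets at the floor on all 4 arrays cannot reach such a p, but whether they account for the whole shortfall was not tested. Among the 27307 brighter probe sets the fit without a trend called 0 and listed 1665, against 1365.35 expected by chance. Among 24708 probe sets off the floor, a filter added after the data were seen, it called 0 and listed 1470, against 1235.4. The groups did not overlap for 31.9% of the brighter probe sets, and chance gives 33.3%. In simulated arrays the test recovered 6.33% of changes of 2 log2 units and 2% of changes of 1 log2 unit. There the estimated spread of each probe set was taken as its true spread and was alike on all 4 arrays. In the real data Rec array 1 stood apart, so these shares are not the recovery of this comparison.

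The 20 genes named by the fixed rule had the smallest unadjusted p with no overlap, and none passed. Several differed little and had nearly identical values within a group. Those higher with Rec were ZNF225-AS1, NAA16, ORC6, ZNF350, DNAI4, GPBP1, PAN3-AS1, RNF114, CDH8 and ZNF271P. ZNF225-AS1, an antisense transcript, had the smallest adjusted p (0.0522 in limma) with a difference of 0.20, and it passed where the adjustment ran over 19775 genes rather than 54613 probe sets (limma adjusted p = 0.0284), with the same difference. NAA16, an auxiliary subunit of an N-terminal acetyltransferase, measured 10.10 ± 0.0029 and 10.31 ± 0.0012, and ORC6, a subunit of the origin recognition complex, 11.70 ± 0.0023 and 11.85 ± 0.00059. CDH8, a cadherin, measured 4.40 ± 0.021 and 5.14 ± 0.042. Those lower were SLC5A3, AKR7A3, GCC1, LAPTM4A, SEPHS2, BHLHE40, SLPI, KIF21A, PGK1 and NPNT. AKR7A3, an aldo-keto reductase, measured 8.68 ± 0.013 and 8.35 ± 0.0088, and NPNT, an integrin ligand of the kidney matrix, 9.79 ± 0.011 and 9.47 ± 0.023. SLPI, a secreted protease inhibitor, differed by −0.30. SLC5A3, BHLHE40 and PGK1 were higher rather than lower when all probe sets of a gene were averaged, by 0.15, 0.24 and 0.0019.

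By size alone, without a test, 183 probe sets were at least 2-fold apart with no overlap, 175 of them higher with Rec and 8 lower. The brightest probe set of a gene made up 23 of the higher and 6 of the lower ones. Another 116 of the higher ones were dimmer probe sets of a gene, and 30 had no gene name. The 23 genes included the interferon-stimulated genes IFIT3, RSAD2, OASL and RIGI, the histone gene H3C6, and MED18, a subunit of Mediator, which differed by 1.45. The 6 lower genes were ABHD14B, EPHB1, FAM50B, EN1, PPP1R9B and NEURL1B. These names were chosen after their values were seen. Of the lower genes only FAM50B lay alike on both Rec arrays (3.31 and 3.37), and the others were lower mainly on Rec array 1. ABHD14B measured 5.88 on Rec array 1 and 7.78 on Rec array 2, against 7.85 ± 0.029 with empty vector. RSAD2 measured 7.28 on Rec array 1 and 5.25 on Rec array 2, against 5.10 ± 0.14, while H3C6 and MED18 were higher on both. The count of 183 fell without Rec array 1 and rose without Rec array 2, where a larger share was lower. Those probe sets were picked anew, and no overlap is easier to reach with 1 array in a group. At 1.5-fold with all arrays 774 were higher and 131 lower.

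**Figure D2:**
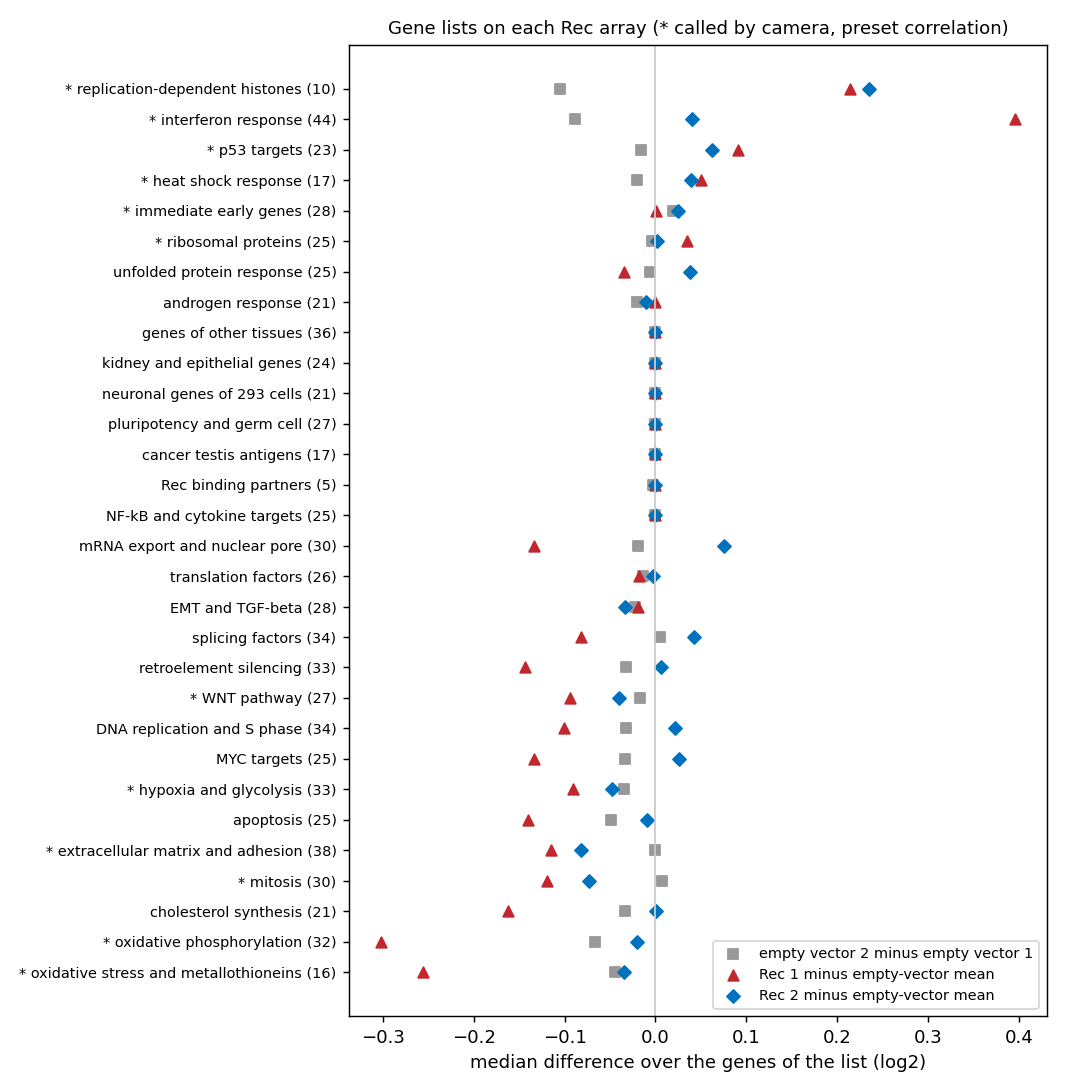
Median log2 difference over the measured genes of each of 30 gene lists, for Rec array 1 and Rec array 2 against the mean of the empty-vector arrays, and for empty-vector array 2 against array 1 (asterisks mark the 12 lists called by camera with its preset correlation). The interferon list lies at 0.40 on Rec array 1 and 0.040 on Rec array 2, and the histone list at 0.21 and 0.24.

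Of 30 gene lists fixed before the data were examined, camera called 12, of which 6 were shifted higher and 6 lower with Rec. The same test called 3 and 5 lists for the other groupings of the 4 arrays into pairs, which do not part Rec from empty vector. With an estimated correlation between genes camera called 0 (smallest adjusted p = 0.645), and fry, which tests whether the genes of a list move on balance one way, also called 0 (smallest adjusted p = 0.298). No list member passed over all probe sets. Chance gives no overlap, in either direction, for 33.3% of genes, and the counts of genes with no overlap below are to be read against that share. Adjusted over the list alone, 5 members of 4 lists passed: CXCL8, TP53I3, PPM1D, EIF3I and PGK1. Over 12289 brighter genes the median difference was −0.038, with −0.067 on Rec array 1 and 0 on Rec array 2. Over all 19775 genes it was 0. The lower medians of lists of expressed genes include this general shift.

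Interferon-stimulated genes were higher on Rec array 1, the array that stood apart, and shifted little on Rec array 2. The list's median difference over 44 genes was 0.24 and its mean 0.39, with camera adjusted p = 3.47e-06, and adjusted p = 0.645 with an estimated correlation. Of the 44 genes 9 lay near the floor on all 4 arrays, and the median was 0.40 among brighter probe sets and off the floor. With 1 array left out, over all or brighter probe sets, the median ran from 0.040 to 0.78. Over all 44 genes it was 0.40 on Rec array 1 and 0.040 on Rec array 2, while the empty-vector arrays differed by −0.089. Of the 44 genes 14 were higher and 2 lower with no overlap, and 0 passed. Chance gives no overlap for 33.3% of genes, so the number without overlap is no sign of a shift by itself. SAMD9 measured 8.27 ± 0.00075 and 8.53 ± 0.048, IRF7, a transcription factor of the interferon response, 6.74 ± 0.023 and 7.58 ± 0.37, and USP18, which removes ISG15 from proteins, 9.20 ± 0.033 and 9.35 ± 0.071. The antiviral gene IFIT3, chosen after its values were seen, measured 12.15 on Rec array 1, 10.59 on Rec array 2 and 10.12 ± 0.21 with empty vector. The call was lost without Rec array 1 (adjusted p = 0.35, and 0.213 among brighter probe sets).

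Probe sets of replication-dependent histone genes gave higher signals with Rec on both arrays. Which forms of these transcripts the probe sets measure was not examined. The list's median over 10 genes was 0.26 and its mean 0.33, with camera adjusted p = 1.29e-05, and adjusted p = 0.645 with an estimated correlation. The median was 0.21 on Rec array 1 and 0.24 on Rec array 2, and the empty-vector arrays differed by −0.11. Of the 10 genes 7 were higher and 0 lower with no overlap, and 0 passed. H2AC6 measured 6.73 ± 0.17 and 7.42 ± 0.037, H4C8 6.34 ± 0.11 and 7.34 ± 0.22, and H2BC5 8.62 ± 0.061 and 8.97 ± 0.12. Histone genes are near-identical copies that probe sets may not tell apart, so single members are uncertain. The list was called in each fit that left out 1 array, over all or brighter probe sets, with adjusted p between 0.00018 and 0.0332.

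**Figure D3:**
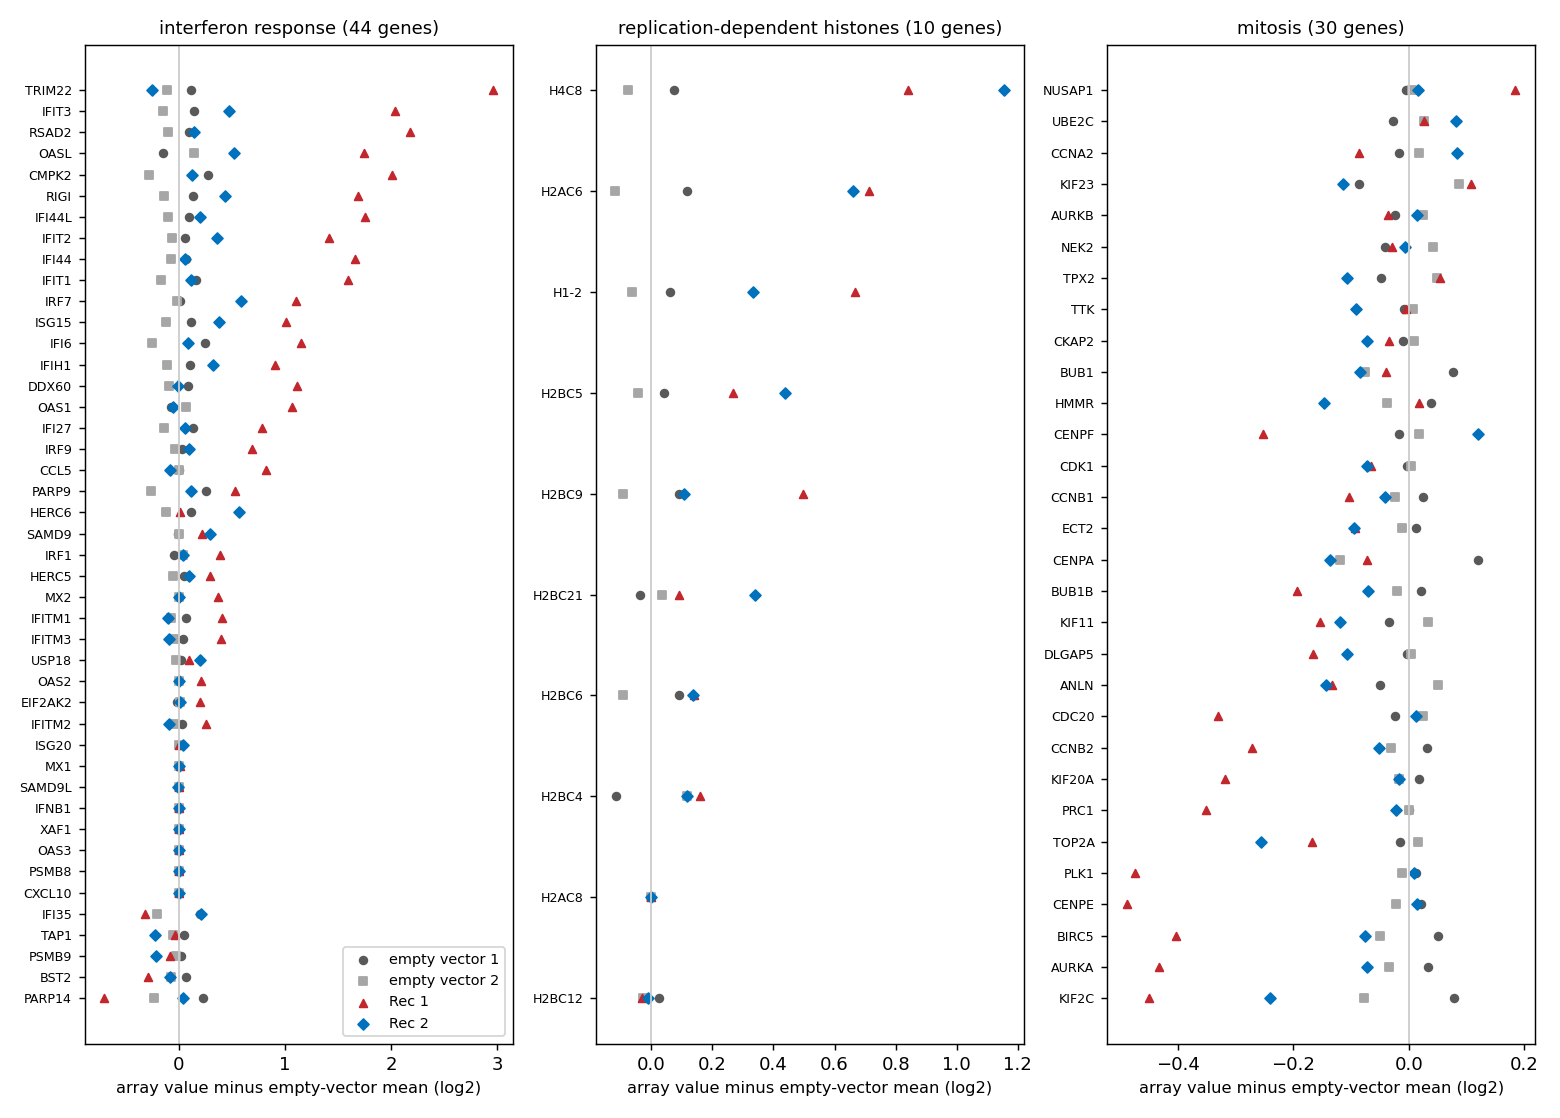
Log2 value of each gene of 3 lists on each of the 4 arrays, minus the mean of the empty-vector arrays, with genes ordered by the difference between the groups. In the interferon panel IFIT3, RSAD2 and TRIM22 lie at 2.03, 2.18 and 2.96 on Rec array 1 and at 0.47, 0.15 and −0.25 on Rec array 2.

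Genes of cell division were slightly lower with Rec, beside a median of −0.038 over brighter genes as a whole. The mitosis list had a median of −0.099 over 30 genes, −0.12 on Rec array 1 and −0.073 on Rec array 2, with 14 genes lower and 1 higher with no overlap. Its camera adjusted p was 1.29e-05, and adjusted p = 0.645 with an estimated correlation. The kinase CDK1 measured 13.33 ± 0.0055 and 13.26 ± 0.0055, ECT2, a regulator of cytokinesis, 11.83 ± 0.018 and 11.74 ± 0.00069, and DLGAP5, a spindle protein, 11.77 ± 0.0053 and 11.64 ± 0.041. The mitosis list was not called when all probe sets of a gene were averaged (adjusted p = 0.183, median −0.073), nor among the brighter probe sets without empty-vector array 2 (adjusted p = 0.0876, median −0.11) or without Rec array 2 (adjusted p = 0.0711, median −0.12). Genes of DNA replication were not called, with a median of −0.063 over 34 genes and adjusted p = 0.459. The p53 target list was called higher, with a median of 0.095 over 23 genes, 0.091 on Rec array 1 and 0.063 on Rec array 2, camera adjusted p = 0.048, and adjusted p = 0.645 with an estimated correlation. PPM1D, a phosphatase that restrains p53, measured 11.79 ± 0.023 and 12.05 ± 0.016, while TP53I3 differed by −0.11 and MDM2 by 0.29. The p53 list was not called when all probe sets of a gene were averaged (adjusted p = 0.112, median 0.094). No fit that left out 1 array, over all or brighter probe sets, called the p53 list, with adjusted p between 0.0553 and 0.444 and medians from 0.032 without empty-vector array 2 to 0.091. Apoptosis genes were not called, with a median of −0.093 over 25 genes and adjusted p = 0.447.

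Matrix and adhesion genes and genes of hypoxia and glycolysis were lower with Rec. Brighter genes as a whole had a median of −0.038, and of −0.067 on Rec array 1. The matrix and adhesion list had a median of −0.098 over 38 genes, −0.12 on Rec array 1 and −0.082 on Rec array 2, with 19 genes lower and 0 higher with no overlap. The integrin subunit ITGA6 measured 9.98 ± 0.11 and 9.51 ± 0.021, ITGB1 13.15 ± 0.019 and 13.04 ± 0.011, and the basement membrane collagen COL4A2 10.34 ± 0.018 and 10.14 ± 0.057. The hypoxia and glycolysis list had a median of −0.085 over 33 genes, −0.090 on Rec array 1 and −0.047 on Rec array 2, with 15 genes lower and 0 higher. The glycolytic enzymes PGK1 and TPI1 differed by −0.14 and −0.095, and P4HA2, a collagen prolyl hydroxylase, measured 10.59 ± 0.075 and 10.27 ± 0.011. Both lists had camera adjusted p = 1.29e-05, and adjusted p = 0.645 with an estimated correlation. When all probe sets of a gene were averaged both were still called, with medians of −0.054 for matrix and −0.026 for hypoxia, and the matrix median was −0.15 among brighter probe sets and −0.19 off the floor. Without Rec array 2 neither was called, with adjusted p of 0.0512 and 0.0761, and of 0.0711 and 0.28 among brighter probe sets.

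Respiratory chain genes had a median of −0.16 over 32 genes, −0.30 on Rec array 1 and −0.021 on Rec array 2. Camera called them lower (adjusted p = 0.000122, and adjusted p = 0.766 with an estimated correlation), with 9 genes lower and 0 higher with no overlap. UQCRC2, a core subunit of complex III, measured 13.29 ± 0.019 and 13.18 ± 0.0092. The call was lost without Rec array 1 (adjusted p = 0.245, and 0.335 among brighter probe sets) and without empty-vector array 1 (adjusted p = 0.137 and 0.109, median −0.12), and was kept with a median of −0.091 when all probe sets of a gene were averaged. The oxidative stress and metallothionein list was called lower, with a median of −0.18 over 16 genes, −0.26 on Rec array 1 and −0.035 on Rec array 2, camera adjusted p = 0.0113, and adjusted p = 0.645 with an estimated correlation. The metallothioneins, which bind zinc and copper, led it: MT1F measured 8.55 ± 0.095 and 8.06 ± 0.092, MT1G 9.13 ± 0.11 and 8.75 ± 0.022, and MT1E 7.13 ± 0.068 and 6.83 ± 0.068. These are close paralogs and uncertain singly. That call was lost without Rec array 1, Rec array 2 or empty-vector array 1, with adjusted p of 0.197, 0.179 and 0.586 and medians of −0.035, −0.26 and −0.17. Among brighter probe sets these adjusted p were 0.127, 0.178 and 0.066, and the medians −0.061, −0.33 and −0.21. With averaged probe sets it was kept, with a median of −0.10. The WNT pathway list had a median of −0.056 over 27 genes (camera adjusted p = 0.0146, and adjusted p = 0.645 with an estimated correlation), with 7 genes lower and 1 higher. LEF1, a transcription factor of the pathway, differed by −0.11. The WNT list was not called among brighter probe sets (adjusted p = 0.0914, median −0.094) or off the floor (0.0655, median −0.11), and was called with averaged probe sets (0.0108, median −0.032). No fit that left out 1 array, over all or brighter probe sets, called the WNT list, with adjusted p between 0.0886 and 0.343. Its medians there ran from −0.028 without empty-vector array 1 to −0.094 without Rec array 2, and to −0.14 without the latter among brighter probe sets.

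Chaperone genes were called slightly higher with Rec, and ribosomal protein genes mainly on Rec array 1. The heat shock list had a median of 0.040 over 17 genes, 8 of them higher and 1 lower with no overlap, with camera adjusted p = 0.0369, and adjusted p = 0.645 with an estimated correlation. Its median was 0.050 on Rec array 1 and 0.040 on Rec array 2. The chaperone DNAJA1 measured 12.36 ± 0.032 and 12.62 ± 0.0041. The call was lost with the sample number as a block (median 0.040, adjusted p = 0.0623) and with trend and robust fitting (adjusted p = 0.0557). It was kept among brighter probe sets (median 0.060), with averaged probe sets (0.068) and after quantile normalization (0.026). No fit that left out 1 array, over all or brighter probe sets, called the list, with adjusted p between 0.0553 and 0.267. Without empty-vector array 2 its median was 0, and 0.051 among brighter probe sets. Ribosomal protein genes had a median of 0.015 over 25 genes, 0.035 on Rec array 1 and 0.0017 on Rec array 2, while the empty-vector arrays differed by −0.0037, with camera adjusted p = 0.0113, and adjusted p = 0.766 with an estimated correlation. RPL35 and RPLP1 differed by 0.066 and 0.093. That list was called without Rec array 2 (adjusted p = 0.000121, and 0.00279 among brighter probe sets) and not without any of the other arrays, where adjusted p lay between 0.0838 and 0.955, the last of these tested as lower. The call was kept with averaged probe sets (median 0.054) and after median centring (median 0.0049), and it was lost among brighter probe sets (adjusted p = 0.0737), off the floor (0.105), with trend and robust fitting (0.0557) and after quantile normalization (0.487, median −0.0024). Immediate early genes were called higher by camera with a median of 0.034 but a mean of −0.012 over 28 genes, and medians of 0.00066 on Rec array 1 and 0.025 on Rec array 2, with camera adjusted p = 0.049, and adjusted p = 0.645 with an estimated correlation. The stress-induced factor ATF3 measured 11.63 ± 0.017 and 12.06 ± 0.083, and PHLDA1 differed by −0.61. That call was lost without empty-vector array 1, Rec array 1 or Rec array 2, with adjusted p of 0.979, 0.159 and 0.435 and medians of 0.033, 0.025 and 0.00066. Among brighter probe sets these adjusted p were 0.864, 0.394 and 0.197, and the medians 0.027, 0.014 and 0.0013. It was also lost with the sample number as a block (median 0.034, adjusted p = 0.132), among brighter probe sets (0.0914, median 0.038), off the floor (0.110, median 0.051) and with trend and robust fitting (0.0744). The unfolded protein response list was not called (adjusted p = 0.14), with a median of 0.0011 over 25 genes, and was called higher without Rec array 1 (adjusted p = 0.0412, but 0.102 among brighter probe sets), after quantile normalization (0.0376, median −0.015) and after median centring (0.0332, median −0.0095). Its member XBP1, a transcription factor of that response, measured 10.53 ± 0.016 and 10.90 ± 0.079.

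Genes of RNA export and processing were not called with the deposited values of the 4 arrays, but were called higher under some alternatives. Averaging all probe sets of a gene, 1 of these, adds dimmer probe sets. Over 4666 genes these differed upward with Rec relative to the brightest, so the averaged calls are not particular to RNA processing. The list of mRNA export and nuclear pore genes had a median of −0.0030 over 30 genes, −0.13 on Rec array 1 and 0.076 on Rec array 2, and splicing factors −0.019 over 34 genes, −0.082 and 0.043. Translation factors had a median of −0.0090 over 26 genes. Camera gave all 3 lists a direction opposite to their median and mean, with adjusted p of 0.298, 0.299 and 0.298, and the export and splicing lists had adjusted p = 0.767 with an estimated correlation. Without Rec array 1 these 2 lists were called higher (adjusted p = 0.00172 and 0.0332, and 0.0174 and 0.0354 among brighter probe sets), as they were after quantile normalization (0.042 and 0.034) and when all probe sets of a gene were averaged (0.00561 and 5.39e-05, with medians of 0.016 and 0.11). EIF3I, a subunit of initiation factor 3, measured 12.62 ± 0.0084 and 12.72 ± 0.0011 (limma adjusted p = 0.0429 over the list alone), and THOC1, a subunit of the THO export complex, 9.97 ± 0.063 and 10.38 ± 0.086.

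Host genes known to bind Rec or to serve its targets differed little. ZBTB16 and ZBTB32, transcriptional repressors, lay at 2.22 and 2.19 on every array, at or near the floor. SGTA, a co-chaperone, differed by 0.0036, and by −0.022 after quantile normalization. STAU1, an RNA-binding protein, differed by −0.22, mainly on Rec array 1. It measured 12.44 on Rec array 1 and 12.75 on Rec array 2, against 12.82 ± 0.0024 with empty vector. XPO1, the nuclear export receptor, differed by −0.11. XPO1 differed by 0.010 without Rec array 1 and by 0.11 when its probe sets were averaged. MYC measured 7.28 ± 0.024 and 7.11 ± 0.013, a difference of −0.18 that did not pass (limma adjusted p = 1). The list of MYC targets, with a median of −0.064 over 25 genes, was not called (adjusted p = 0.523), nor were the androgen response genes (median 0 over 21 genes, adjusted p = 0.756) or the 5 measured binding partners (median 0, adjusted p = 0.916). IFITM1, an interferon-induced membrane protein, differed by 0.16, and by −0.096 without Rec array 1.

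Endogenous retroviral genes gave 10 probe sets. A probe set of ERVK13-1, a HERV-K locus, measured 6.13 ± 0.067 and 6.54 ± 0.51, a difference of 0.41 with overlapping groups. A probe set of ERVW-1 differed by 0.21, also with overlap. It measured 3.31 on Rec array 1 and 2.55 on Rec array 2, against 2.72 on both empty-vector arrays. The other probe sets lay at or near the floor on all 4 arrays. Genes that silence or restrict retroelements were not called, with a median of −0.041 over 33 genes and adjusted p = 0.403. Among them ZNF91, a zinc finger protein that represses retrotransposons, measured 8.34 ± 0.087 and 9.06 ± 0.0046.

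The remaining lists were not called. NF-kB and cytokine targets had a median of 0 over 25 genes (camera adjusted p = 0.265), 11 of which lay near the floor on all 4 arrays. The chemokine gene CXCL8 measured 7.05 ± 0.0013 and 7.22 ± 0.014. Genes of TGF-beta signalling and epithelial-mesenchymal transition had a median of −0.017 over 28 genes (camera adjusted p = 0.403). Those of cholesterol synthesis had a median of −0.11 over 21 genes (camera adjusted p = 0.299), with −0.16 on Rec array 1 and 0.00061 on Rec array 2. Pluripotency and germ cell genes, cancer testis antigens, neuronal genes, and kidney and epithelial genes had medians of 0, with camera adjusted p of 0.523, 0.635, 0.298 and 0.523. In these lists 18 of 27, 10 of 17, 12 of 21 and 13 of 24 genes lay near the floor on all 4 arrays. Their medians therefore say little of the members that were expressed. SNAP25, a synaptic vesicle fusion protein, measured 5.06 ± 0.0066 and 5.91 ± 0.098. Markers of other tissues had a median difference of 0 (mean −0.011, tested as higher, adjusted p = 0.523), and 34 of 36 genes lay near the floor on all 4 arrays.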

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

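Of the tests in this part, those of the labelled amount, of the direction of shared differences and both tests of the interferon list were chosen after the results had been seen. Spiked-in bacterial and phage control transcripts, which lie outside the comparison of cell transcripts, had signal above the level of the empty-vector arrays. Over 9 such probe sets Rec array 1 exceeded the empty-vector mean by a median of 1.36 log2 units (0.75 to 1.62), Rec array 2 by 0.15 (0.073 to 0.35), and the empty-vector arrays differed by 0.0051.

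Rec array 1 also lay farther from the empty-vector arrays than Rec array 2 in cell transcripts, with 709 brighter probe sets over 1 log2 unit from the median of the 4 arrays. Degraded RNA is argued against. The 3' minus 5' difference of ACTB on that array minus the highest of the other 3 arrays was −0.42, and that of GAPDH also lay lower. A difference in scale left in the deposited values is argued against, since 102% as many probe sets remained beyond that distance after quantile normalization. The deposited arrays already had similar distributions, so this could not test a difference in scale that was removed before deposit. Leaving out the interferon list lowered the number of genes beyond that distance by 6.78%, from 177 to 165. With 44 measured genes the list could not have made up most of the 177. The test therefore says nothing of interferon-stimulated genes outside the list. A smaller amount of labelled sample on that array, which would raise spiked-in controls relative to cell transcripts, may contribute, given their shift of 1.36. Whether the array showed more of a response shared with Rec array 2 cannot be told apart from noise of the array: 65.8% of 1044 probe sets, which are not independent of each other, over 1 log2 unit apart between the arrays numbered 1 went the same way between the arrays numbered 2, with 535 of 681 among the higher and 152 of 363 among the lower.

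The interferon list was higher on Rec array 1 (median 0.40) far more than on Rec array 2 (0.040), where the shift was below the size of the difference between the empty-vector arrays (−0.089). A shift that genes of like level share on Rec array 1 is argued against, since 0 of 10000 random lists matched on mean level reached its median there, the smallest share that 10000 draws can give being 0.01%. Whether the shift was confined to Rec array 1 cannot be told apart from a small shift on both: 2 of 10000 random lists lay as high on Rec array 2, but 3 of 10000 also lay as low between the empty-vector arrays, so the list's genes varied together without Rec. A response of 1 culture to transfection, or to Rec at a level that differed between the cultures, stays open as a biological hypothesis and was not tested, because the amount of Rec in each culture was not analysed here.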

How the results depend on the processing

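The test of the calls made with 1 array left out was chosen after these calls had been seen. With 2 arrays a group the counts of called probe sets and genes were 0 in each direction under the filter on dim probe sets, median centring, trend with robust fitting, the sample number as a block and the filter against the floor, the last of which was added after the data were seen. Quantile normalization gave 1 probe set higher, a dimmer probe set of ZNF230 (adjusted p = 0.0186), for a cause that was not tested. The fit on averaged probe sets gave 1 gene higher, ZNF225-AS1, with the same difference (0.20) and adjusted over 19775 genes rather than 54613 probe sets. Leaving out 1 array called 387 to 2503 probe sets higher, 684 to 1292 lower, 133 to 652 genes higher and 247 to 436 lower. Of these calls 63.9% had a mean difference under 0.1, which fits nearly identical values near the floor, and with the brighter probe sets alone, also added afterwards, each of these counts was 0. The 183 probe sets at least 2-fold apart numbered 104 to 963 with 1 array left out, lowest without Rec array 1 and highest without Rec array 2, and 905 at 1.5-fold. Of 3 splits of the arrays into pairs 1, the real one, gave as many, and the highest of the others gave 45; 3 splits are too few for a share under 0.05. Lists called numbered 4 to 8 with 1 array left out, 0 with an estimated correlation and 0 with fry, against 9 to 14 otherwise. Over the alternatives the adjusted p of the called lists ranged as follows: interferon 1.83e-12 to 0.645, histones 2.78e-07 to 0.645, mitosis 3.84e-05 to 0.645, matrix 7.91e-06 to 0.645, hypoxia 5.59e-05 to 0.645, oxidative phosphorylation 0.000124 to 0.766, oxidative stress 0.00561 to 0.645, WNT 0.0108 to 0.645, p53 0.00369 to 0.645, heat shock 0.0145 to 0.645, immediate early 0.0244 to 0.979, ribosomal 0.000121 to 0.955.

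The arrays share sample numbers, but nothing in the labels says that a number marks a shared culture or day, and same-numbered arrays did not deviate together (r = −0.0209 across 27307 probe sets, which are not independent). With the sample number as a block 0 probe sets were called higher and 0 lower, 1811 had an unadjusted p under 0.05 and 10 lists were called, with the heat shock (adjusted p = 0.0623) and immediate early (adjusted p = 0.132) calls lost.

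Several small values turned direction, for causes that were not tested. SGTA differed by −0.022 after quantile normalization and −0.0071 after median centring. With 1 array left out XPO1 ranged from −0.23 to 0.010 and IFITM1 from −0.096 to 0.41. With all probe sets of a gene averaged, SLC5A3 differed by 0.15, BHLHE40 by 0.24, PGK1 by 0.0019 and XPO1 by 0.11. Averaging adds the dimmer probe sets of a gene. Over 4666 genes these differed upward with Rec relative to the brightest, by a median of 0.10 on Rec array 1 and 0.042 on Rec array 2. Turns upward under averaging go with that gap, but whether it accounts for each of them was not tested. The direction given by the list test turned for lists with these medians: after quantile normalization MYC targets (−0.049), androgen response (−0.0040), DNA replication (−0.047) and cancer testis antigens (−0.0011); with the block, androgen response (0); with averaged probe sets, binding partners (0), DNA replication (0.017) and retroelement silencing (−0.013); and genes of other tissues among brighter probe sets (−0.033), after median centring (−0.011) and in fry (0). With 1 array left out it turned in at least 1 fit for lists whose medians ranged as follows: binding partners 0 to 0, MYC targets −0.13 to 0.026, androgen response −0.033 to 0, NF-kB targets 0 to 0.0013, DNA replication −0.10 to 0.022, apoptosis −0.14 to −0.0093, ribosomal proteins 0.0017 to 0.035, mRNA export −0.16 to 0.080, splicing factors −0.082 to 0.043, cancer testis antigens −0.095 to 0.016, retroelement silencing −0.14 to 0.0062, epithelial-mesenchymal transition −0.037 to 0, neuronal genes −0.045 to 0.11, kidney genes −0.029 to 0, genes of other tissues −0.034 to 0. Of 503 list values under the alternatives 359 kept their direction and side of the threshold, 11 gained a call, 91 lost one and 42 turned; of 393 values of 27 named genes 374 kept both, 9 gained a call and 10 turned.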

Other observations

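The groups of genes and probe sets in this part, and the tests of dimmer probe sets, were chosen after the data had been seen; the test of DNAI4 was not. Zinc finger genes, many of which encode transcriptional repressors, recurred among the named genes and are given here by value only. Of 502 genes with a ZNF symbol 387 were among the brighter ones, with a median difference of 0.089, 0.026 on Rec array 1 and 0.11 on Rec array 2, and 0 between the empty-vector arrays. Among them 129 were higher and 22 lower with no overlap. Since these genes were picked from the same 4 arrays, no p is given for them. Unlike the interferon list, these genes had the larger median on Rec array 2, and the difference between the arrays was not tested.

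A few genes of cilia and sperm cells were among the 23 genes at least 2-fold higher with no overlap. Besides DNAI4 these were CFAP53, a cilia protein, at 4.07 ± 0.17 and 5.11 ± 0.17, SPATA17 at 3.75 ± 0.37 and 4.76 ± 0.20, and TSGA10 at 3.98 ± 0.035 and 5.18 ± 0.21 (SD, n = 2). No list of such genes had been fixed, and whether they exceed the number that chance gives was not tested. A second probe set of DNAI4 was higher by 1.55, which argues against a sequence peculiar to 1 probe set as the whole difference.

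Dimmer probe sets of a gene differed upward with Rec relative to its brightest one. The median gap within a gene was taken over 4666 genes with another probe set of mean at least 5. It was 0.10 on Rec array 1, 0.042 on Rec array 2 and −0.014 between the empty-vector arrays, so in size it was not confined to Rec array 1. The bootstrap 95% interval on Rec array 2 was 0.036 to 0.048. That interval is over genes, which are not independent, and does not measure the spread between arrays. Whether the gap on Rec array 2 exceeds that spread cannot be told from 1 difference between empty-vector arrays. With mean level matched, the gap remained, at 0.12 on Rec array 1 and 0.039 on Rec array 2. Between the empty-vector arrays it was 0.0040. The lower level of dimmer probe sets is therefore argued against as the whole of the gap seen on these arrays. With 1 difference between empty-vector arrays, whether the matched gap on Rec array 2 exceeds the spread between arrays cannot be told either. Such probe sets often lie in introns or alternative 3' ends, so retained or incompletely processed transcripts may be a candidate explanation, but the positions of the probes were not used here and a difference in hybridization between the groups stays open.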
